A study of Arabidopsis thaliana with 12 samples.

How the data were processed

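Total RNA from vegetative rosettes of wild type, atx1 and MYO-OX, each watered or under water deficit, was labelled as biotinylated cRNA and hybridized to Affymetrix ATH1 arrays, with 2 biological replicates per group and 12 arrays in all. The values used were the log2 signals deposited by the authors, which the authors made from the scanned arrays by robust multi-array averaging (RMA). The version of RMA is not given in the sources used here. Of 22810 probe sets, 64 control probe sets were set apart and 22746 were tested. The arrays carry no counts, so their number limits the precision.

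Probe sets were joined to genes through the annotation table of the array, which listed 14016 probe sets, 13513 of them with 1 gene and 503 with several. Of these, 13436 were matched to a locus of the TAIR10.1 annotation, which was used for names and for which genes neighbour each other. The probe sets with 1 gene stood for 13355 genes, 1557 with a symbol. Another 8730 probe sets that are not controls were not listed and were tested without a gene name. No probe set was named for ATX1 or MTM1 in these tables, and their levels were not analysed here.

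A linear model with 1 mean per group was fitted to all 12 arrays in R 4.3.3 with limma 3.58.1, with 6 residual degrees of freedom and 2.34 prior degrees of freedom from empirical Bayes moderation. The model gave 11 comparisons: the response to water deficit in each of 3 genotypes, each pair of genotypes within each water state, and the difference of the atx1 and of the MYO-OX response from that of wild type. P values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a probe set was called at an adjusted p under 0.05. Gene lists with at least 3 measured members, 31 in all, were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within each comparison. Of the lists, 28 with 513 members were fixed before the data were examined, of which 60 members were measured and 8 lists had enough members. Measured here means that the annotation table named a probe set for that gene alone. Other members may lie among the probe sets without a gene name, so counts of members describe only the named part of a list. A further 23 lists were added afterwards from the annotation, so their tests carry less weight than those of the lists fixed beforehand. Response sizes were compared over probe sets chosen in the genotype left out of the comparison, with fry in limma weighted by the direction of change and adjusted over 3 such tests. The correlation expected from shared control arrays was taken from 100 simulated data sets.

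The comparisons, the alternatives and the rule for the genes named were fixed before any change was looked at. The rule named ATX1 and MTM1, a panel of which only COR15A was measured under its name, and up to 2 called members with the largest change from each of the 12 lists with the highest share of called members. Outside the lists it named the 5 raised and 5 lowered called genes with the largest change whose probe set matched 1 gene with a symbol and, except for a difference of responses, whose groups of arrays did not overlap. A gene with several probe sets was taken at the probe set with the highest mean.

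The alternatives were the replicate number as a block, median centring of each array, quantile normalization repeated, the dimmest 40% of probe sets left out, an intensity trend with a robust prior, only the arrays of the comparison, 1 probe set per gene, and each array left out in turn. Covariates from the hybridization, GAPDH, actin and ubiquitin control probe sets and a crossed replicate block were added after the data were seen. The procedure was tested on simulated data of the same size in 10 data sets. It recovered 15.4%, 70.6%, 92.2% and 97% of changes of 1, 2, 3 and 4 on the log2 scale, with 4.31% false calls among those called. In each data set 200 probe sets were changed, and the noise was independent with the same spread in every group. The measured water-deficit responses had more calls, and some groups of arrays deviated together, so these rates may not hold for them. The image files of the arrays were not used here.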

Results

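RNA from vegetative rosettes of Arabidopsis thaliana was measured on Affymetrix ATH1 arrays. The 12 arrays fell into 6 groups, given by 3 genotypes and 2 water states, with 2 biological replicates in each group. The genotypes were Columbia-0 wild type, the atx1 mutant, which lacks the chromatin modifier ATX1 (ARABIDOPSIS TRITHORAX 1), and MYO-OX, a line named for overexpression of the myotubularin homolog MYO1. Plants were either kept watered or deprived of water to a set relative water content. Levels are log2 signals given as mean ± SD over the arrays of a group, n = 2, and changes are log2 differences with the limma standard error (SE). The number of arrays limits the precision. The replicates of a group correlated at 0.928 (watered MYO-OX) to 0.987 (wild type under water deficit) across probe sets, which are not independent replicates. The first principal component held 58% of the variance. On it all 6 watered arrays lay between -92.32 and -49.79, the wild-type and MYO-OX water-deficit arrays between 85.77 and 111.1, and the atx1 water-deficit arrays at -10.54 and 27.53.

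The control probe sets differed between groups. The spiked hybridization controls averaged 9.845 ± 0.265 in atx1 under water deficit and 8.481 ± 0.438 in watered wild type. The difference between the 3' and 5' GAPDH control probe sets was 1.742 and 1.193 on the atx1 water-deficit arrays, and at most 1.088 on any other array. These facts belong beside every gene group described for atx1 under water deficit.

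**Figure D1:**
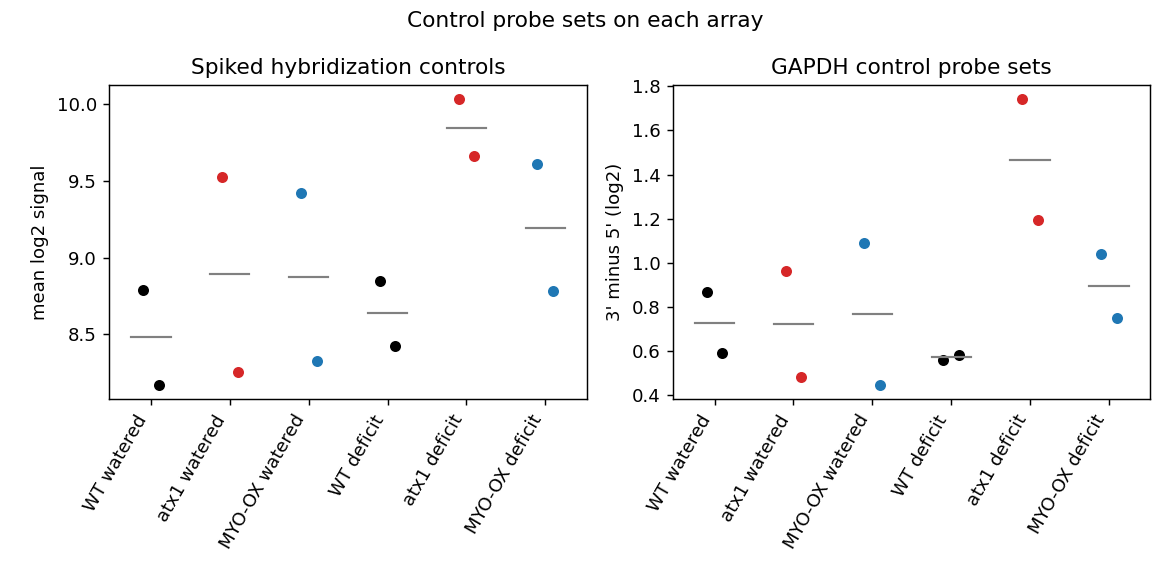
Mean log2 signal of the spiked hybridization controls (left) and log2 difference between the 3' and 5' GAPDH control probe sets (right) on each of the 12 arrays, by group, with each point an array and each grey line the mean of its group. The atx1 water-deficit arrays hold the highest values in both panels, with group means of 9.845 and 1.468.

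The first comparison asked how wild-type rosettes responded to water deficit. Most measured genes for dehydration-induced proteins rose. LEA18 (AT2G35300), a late embryogenesis abundant protein gene, rose 97.8-fold, from 4.04 ± 0.084 to 10.65 ± 0.504 (SE 0.588, adjusted p = 0.000378). COR15A (AT2G42540), which encodes a chloroplast-targeted protective protein, rose 11.8-fold, from 9.812 ± 0.385 to 13.37 ± 0.137 (SE 0.517, adjusted p = 0.00253). Of the 8 measured genes for dehydration-induced proteins, 7 rose and 1 did not pass the test, and 7 rose when adjusted over the list alone. Their median change was 4.68 (camera adjusted p = 1.22e-07). With an estimated correlation, the adjusted p was 0.171. Both measured heat shock genes rose, HSP17.6C (AT1G53540) by 3.48 (adjusted p = 0.000692) and HSP22 (AT4G10250) by 2.43 (adjusted p = 0.00103). Among genes outside the lists, the sugar transporter gene SWEET4 (AT3G28007) rose 41.6-fold (SE 0.192, adjusted p = 3.14e-05), and APL4 (AT2G21590), for a subunit of ADP-glucose pyrophosphorylase in starch synthesis, rose 28.3-fold (SE 0.195, adjusted p = 3.19e-05). In watered wild type 18.8% of probe sets lay at or below LEA18 and 11.1% at or below APL4, levels not shown to lie above background, so these folds are not exact. SWEET15 (AT5G13170), a sugar transporter gene of senescing leaves, rose 39.4-fold (adjusted p = 0.00141).

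Some genes of cell wall loosening and photosynthesis fell in wild type. The expansin gene EXPA8 (AT2G40610), whose product loosens cell walls, fell 36.1-fold, from 9.87 ± 0.239 to 4.695 ± 0.242 (SE 0.442, adjusted p = 0.000319), and XTH16 (AT3G23730), for a xyloglucan endotransglucosylase, fell by 4.47 (adjusted p = 0.00134). Of the 9 measured expansin and xyloglucan endotransglucosylase genes, 5 fell and 4 did not pass the test, and 5 fell when adjusted over the list alone (camera adjusted p = 0.00133, median -1.89). Of the 7 measured light harvesting and photosystem genes, 5 fell and 6 fell when adjusted over the list alone, with a median of -1.38 (camera adjusted p = 0.000489). For these lists the adjusted p = 0.171 and the adjusted p = 0.273 with an estimated correlation. Both measured guard cell genes fell, GC1 (AT1G22690) from 9.165 ± 0.334 to 3.772 ± 0.204 (SE 0.446, adjusted p = 0.000306) and FAMA (AT3G24140), a transcription factor of guard cell differentiation, by 0.97 (adjusted p = 0.00404). BCAT4 (AT3G19710), for the methionine aminotransferase that begins aliphatic glucosinolate side-chain elongation, fell by 3.46 (adjusted p = 0.00134), and DRT100 (AT3G12610) fell 50.7-fold (SE 0.585, adjusted p = 0.000658). In wild type under water deficit at most 22% of probe sets lay at or below DRT100, XTH16 or GC1. These levels are not shown to lie above background, so the falls of these genes are not exact. The 3 measured oxidative stress genes did not move together. ALDH7B4 (AT1G54100) rose by 3.15 and TAPX (AT1G77490), the thylakoid ascorbate peroxidase gene, fell by 1.67, so that the median of -0.17 and the test were negative and the mean of 0.44 positive (camera adjusted p = 0.885; adjusted p = 0.925 with an estimated correlation). The TAPX call ended without wild-type water-deficit replicate 1 (adjusted p = 0.0696) and without wild-type watered replicate 1 (adjusted p = 0.0645), in limma.

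In total, limma called 4466 of 22746 probe sets in wild type, 2037 higher and 2429 lower under water deficit, of which 3953 changed at least 2-fold. With each array centred on its own median, the median change over all probe sets moved from 0.01 to 0.12, and the calls were split into 2563 higher and 1996 lower. The count was 1839 without watered replicate 1, 1441 without water-deficit replicate 1 and 2882 without water-deficit replicate 2. Of the 29 named genes called, 20 were called whichever array was left out, and each gene named above except TAPX was among them.

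The same question was put to MYO-OX. LEA4-5 (AT5G06760), a further late embryogenesis abundant gene, rose 134-fold, from 5.604 ± 0.676 to 12.67 ± 0.302 (SE 0.678, adjusted p = 0.000482), and COR15A rose 11.5-fold (SE 0.517, adjusted p = 0.0024). Of the 8 dehydration-induced protein genes, 7 rose, also when adjusted over the list alone, with a median of 4.24 (camera adjusted p = 2.03e-06; adjusted p = 0.168 with an estimated correlation). HSP17.6C, HSP22, SWEET15 and SWEET4 rose by 2.95, 2.15, 5.14 and 4.79. BETA-VPE (AT1G62710), for a vacuolar processing enzyme, rose 22.4-fold (adjusted p = 0.00043). EXPA8 fell 17.2-fold, from 9.066 ± 0.0217 to 4.965 ± 0.0537 (SE 0.442, adjusted p = 0.000735), and XTH16 fell 34.5-fold (SE 0.553, adjusted p = 0.000746). Under water deficit 21.3% of probe sets lay at or below XTH16 in MYO-OX, a level not shown to lie above background, so its fold is not exact. Of the 9 expansin and xyloglucan endotransglucosylase genes, 5 fell and 6 fell when adjusted over the list alone, with a median of -2.16 (camera adjusted p = 0.000882; adjusted p = 0.168 with an estimated correlation). Of the 7 light harvesting and photosystem genes, 4 fell and 6 fell when adjusted over the list alone (camera adjusted p = 0.00467; adjusted p = 0.412 with an estimated correlation), a call that ended without watered MYO-OX replicate 2 (adjusted p = 0.159) and with dim probe sets left out (adjusted p = 0.0541), over a range of 0.00037 to 0.159. GC1 fell by 5.42, BCAT4 by 3.34 and GSTU20 (AT1G78370), a glutathione transferase gene, by 4.26 (adjusted p = 0.000482). The fall of GC1 is not exact either, with 20.4% of probe sets at or below it in MYO-OX under water deficit. limma called 5616 probe sets, 2433 higher and 3183 lower. Median centring moved the median change from 0.04 to 0.15 and split the calls into 2999 higher and 2557 lower. Without water-deficit replicate 2 of MYO-OX the count was 2686, and with only the 4 arrays of the comparison it was 1176, with 17 of the 31 named genes still called and HSP22 not among them.

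In atx1 fewer genes passed the same test. EXLB1 (AT4G17030), an expansin-like gene, rose 45.5-fold from 5.737 ± 0.64 to 11.24 ± 0.351 (SE 0.324, adjusted p = 0.000453), and CYP71B31 (AT3G53300), a cytochrome P450 gene, rose 18.3-fold from 3.723 ± 0.0286 to 7.915 ± 0.334 (SE 0.228, adjusted p = 0.000453). HIS1-3 (AT2G18050), for a drought-inducible linker histone, rose by 5.15 (adjusted p = 0.00628) and PUB19 (AT1G60190), for a U-box ubiquitin ligase, by 3.38 (adjusted p = 0.000962). GC1 fell 19.6-fold, from 7.89 ± 0.629 to 3.6 ± 0.238 (SE 0.446, adjusted p = 0.00337). Only 9.3% of probe sets lay at or below watered CYP71B31 and 6.04% at or below GC1 under water deficit, levels not shown to lie above background, so these folds are not exact. Of the 8 dehydration-induced protein genes, 4 rose and 7 rose when adjusted over the list alone, with a median of 2.98 (camera adjusted p = 1.25e-06; adjusted p = 0.233 with an estimated correlation). LEA18 was among them with a 12.2-fold rise, from 4.278 ± 0.114 to 7.882 ± 1.54 (adjusted p = 0.0168), which did not pass without watered atx1 replicate 1 (adjusted p = 0.0933) or replicate 2 (adjusted p = 0.102). COR15A was not called, at 9.971 ± 1.31 watered and 11.2 ± 0.378 under water deficit (change 1.23, adjusted p = 0.296). It was called without watered atx1 replicate 1, with a change of 2.16 (adjusted p = 0.0358). No expansin or xyloglucan endotransglucosylase gene of the 9 passed limma over all probe sets, and 3 fell when adjusted over the list alone, with a median of -0.94 (camera adjusted p = 0.00661; adjusted p = 0.233 with an estimated correlation; adjusted p = 0.0694 with the GAPDH difference as a covariate, in a range of 0.00432 to 0.0694). The 7 light harvesting and photosystem genes lay lower as a list (camera adjusted p = 0.0333). That test did not pass with repeated quantile normalization (adjusted p = 0.0782) or with dim probe sets left out (adjusted p = 0.127). It also ended with the hybridization (adjusted p = 0.111) and GAPDH covariates (adjusted p = 0.217). EXPA8 stood at 8.474 ± 0.897 under water deficit in atx1, and the heat shock genes HSP17.6C and HSP22 were not called (adjusted p = 0.399 and 0.739). The GAPDH 3'-5' difference was 1.468 in this water-deficit group and 0.721 in watered atx1.

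For atx1 the count was 725 probe sets, 477 higher and 248 lower, of which 677 changed at least 2-fold. It was 252 without watered replicate 1, 177 without watered replicate 2 and 229 without water-deficit replicate 2. With only the 4 atx1 arrays limma called 0 probe sets, against 3599 at an unadjusted p under 0.05. With the hybridization controls as a covariate it was 2259, and with the GAPDH difference 3908. Of the 15 named genes called, 6 were called whichever array was left out (GC1, EXLB1, HIS1-3, ZW9, CYP71B31 and PUB19), and none was called with the 4 arrays alone.

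Setting the 3 responses side by side asked how far the genotypes differed in the size of the response. Across the 22746 probe sets, which are not independent replicates, the wild-type and MYO-OX responses correlated at Pearson r = 0.934 (Spearman rho = 0.868) with a slope of 0.996. The wild-type and atx1 responses correlated at r = 0.759 (rho = 0.685) with a slope of 0.462. Of the wild-type calls, 3815 were called in the same direction in MYO-OX, against 218 higher and 340 lower expected for independent sets, and none in the opposite direction. The wild-type and atx1 calls shared 575 in the same direction and 0 in the opposite one. In all 3 genotypes 342 probe sets rose and 215 fell. The size of the response was then compared over the 5616 probe sets called in MYO-OX, the genotype left out of the comparison. The spread used for these calls came from all 6 groups, so the choice was not fully independent of wild type and atx1. It also left out probe sets that responded in atx1 alone. The share therefore describes the response that MYO-OX showed, not the size of the whole atx1 response. Over all probe sets the root mean square change was 1.1 in wild type, 1.17 in MYO-OX and 0.671 in atx1. The mean response in the direction of the MYO-OX change was 1.67 in wild type and 0.81 in atx1, a share of 0.484 (fry in limma, adjusted p = 0.0212 over 3 such tests). It was smaller in atx1 for 91.8% of these probe sets. Over the 4466 chosen in wild type, the atx1 response was 0.473 of the MYO-OX response (fry in limma, adjusted p = 0.0128). Over the 725 chosen in atx1, the MYO-OX response was 1.02 of the wild-type response (fry in limma, adjusted p = 0.847). The share in atx1 was 0.699 with the hybridization controls as a covariate and 0.996 with the GAPDH difference as one, and fry was not passed with either.

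**Figure D2:**
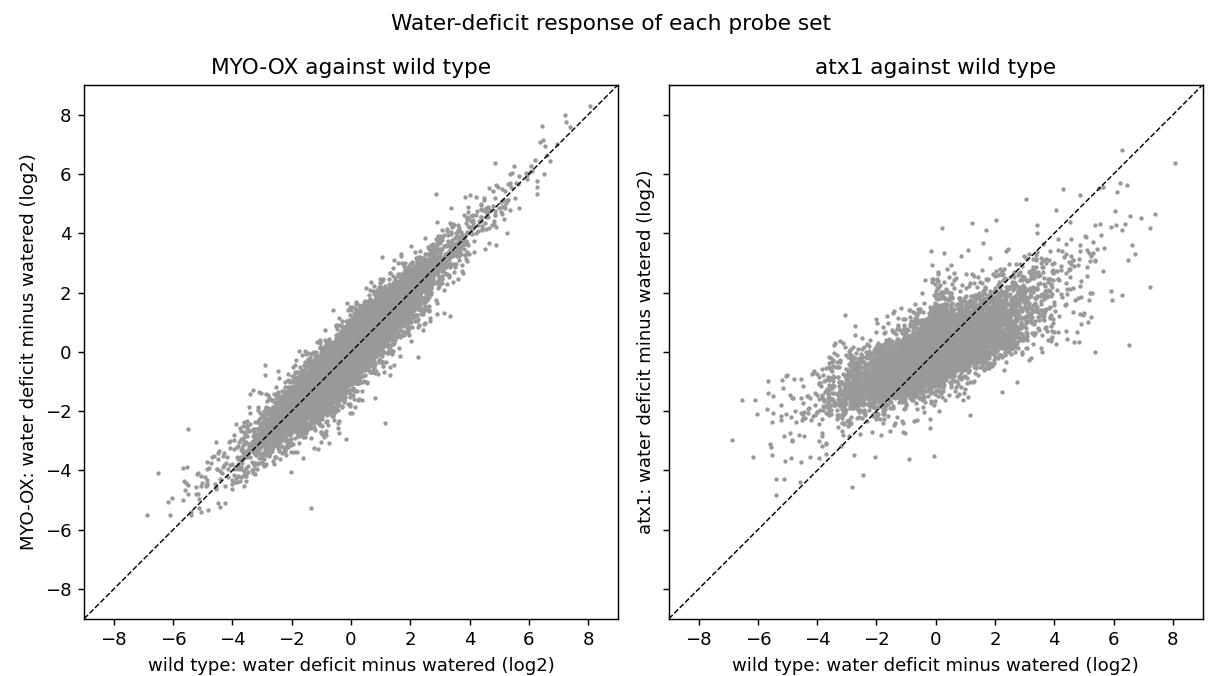
Water-deficit response (log2, water deficit minus watered) of each probe set in MYO-OX (left) and in atx1 (right) on the vertical axis against that in wild type on the horizontal axis, with each point a probe set and the dashed line marking equal responses. The points follow the line for MYO-OX (r = 0.934, slope 0.996) and form a flatter cloud for atx1 (r = 0.759, slope 0.462).

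Comparing atx1 with wild type in watered plants asked how the mutant differed without stress. The background accession of the atx1 line is not given in the sources used here. A difference of background therefore cannot be told apart from an effect of the mutation. GILT (AT4G12960), of the gamma-interferon-inducible lysosomal thiol reductase family, was 28.9-fold higher in atx1, at 8.538 ± 0.28 against 3.686 ± 0.101 (SE 0.262, adjusted p = 0.000151). Only 8.19% of probe sets lay at or below its wild-type level, so the fold is not exact. ZW9 (AT1G58270) was 59.9-fold lower, at 4.653 ± 0.243 against 10.56 ± 0.138 (SE 0.281, adjusted p = 0.000151). IAA29 (AT4G32280), an Aux/IAA repressor gene of the auxin response, was 6.48-fold lower (5.097 ± 0.575 against 7.793 ± 0.127, SE 0.272, adjusted p = 0.00301), the 1 of 4 measured auxin response genes to pass (camera adjusted p = 0.074; adjusted p = 0.422 with an estimated correlation). The jacalin lectin genes JAL33 (AT3G16450) and JAL22 (AT2G39310) were lower, with changes of -4.08 (adjusted p = 0.00453) and -3.94 (adjusted p = 0.00202). ECS1 (AT1G31580), for a cell wall protein, was 110-fold lower, at 6.634 ± 2.33 against 13.42 ± 0.207 (SE 0.856, adjusted p = 0.00674), which did not pass without watered wild-type replicate 1 (adjusted p = 0.071). Dehydration-induced protein genes did not differ detectably, with 0 of 8 called by limma, also when adjusted over the list alone (camera adjusted p = 0.425; adjusted p = 0.708 with an estimated correlation), and COR15A differed by 0.16 (adjusted p = 0.99). The dehydration and ABA genes listed from the annotation passed (camera adjusted p = 0.0329). They did not with only the arrays of the comparison (camera adjusted p = 0.0631) or the hybridization covariate (camera adjusted p = 0.0567). ZAT10, of the drought and ABA transcription factors, was lower by 2.99 (SE 0.541, limma adjusted p = 0.0308). With only the arrays of the comparison ZAT10 did not pass (limma adjusted p = 0.113). The 4 measured flavonoid genes lay lower as a list, with changes such as -1.74 in DFR and -2.19 in UGT75C1. None passed on its own or when adjusted over the list alone, and the list test (camera adjusted p = 0.0182; adjusted p = 0.579 with an estimated correlation) ended without watered wild-type replicate 1 (adjusted p = 0.118) and without watered atx1 replicate 1 (adjusted p = 0.0516), in a range of 0.000723 to 0.118.

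In watered plants 501 probe sets differed between atx1 and wild type, 272 higher and 229 lower in atx1. Median centring split the calls into 206 higher and 292 lower. The count was 101 and 220 without the first and second watered wild-type replicate, 204 and 176 without the first and second watered atx1 replicate, 60 with only the arrays of the comparison and 986 with the GAPDH covariate. Of the 12 named genes called, 6 were called whichever array was left out (IAA29, GILT, ZW9, JAL33, JAL22 and 2A6). With only the arrays of the comparison 6 of the 12 stayed called, and IAA29 (adjusted p = 0.0777, in a range of 0.0012 to 0.0777) and ECS1 did not.

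Watered atx1 differed from watered MYO-OX in many of the same named genes. The atx1 arrays were those of the comparison with wild type, so the 2 comparisons are not independent and shared genes do not add separate evidence. GILT was 28-fold higher (SE 0.262, adjusted p = 0.000124), and ZW9 62.9-fold (SE 0.281, adjusted p = 0.000107) and IAA29 13.9-fold lower in atx1 (SE 0.272, adjusted p = 0.000542). QQS (AT3G30720), an orphan gene linked to starch content, was 15.2-fold lower, at 3.825 ± 0.138 against 7.754 ± 0.725 (adjusted p = 0.00114). Only 9.61% of probe sets lay at or below GILT in MYO-OX and 12.4% at or below QQS in atx1, so these folds are not exact. No list fixed beforehand passed, the nearest being the flavonoid genes (camera adjusted p = 0.0546; adjusted p = 0.755 with an estimated correlation). Of 591 probe sets called, 286 were higher and 305 lower, and median centring moved the median difference from 0.02 to -0.08 and split the calls into 212 higher and 330 lower. The count was 256 without watered atx1 replicate 1, 201 without watered atx1 replicate 2 and 2689 without watered MYO-OX replicate 2. With the arrays of the comparison alone limma called 0, against 1951 at an unadjusted p under 0.05, and it called 908 and 1060 with the hybridization and GAPDH covariates.

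Comparing atx1 with wild type under water deficit asked whether the mutant reached the same expression state. Several named genes that fell in drying wild type stood higher in atx1, though GC1, at 3.6 ± 0.238 against 3.772 ± 0.204, did not. EXPA8 was 13.7-fold higher, at 8.474 ± 0.897 against 4.695 ± 0.242 (SE 0.442, adjusted p = 0.00207), and BCAT4 10.9-fold higher, at 12.25 ± 0.113 against 8.81 ± 0.801 (SE 0.428, adjusted p = 0.00257). DRT100 and MSRB5 (AT4G04830), a methionine sulfoxide reductase gene, were higher by 5.53 (adjusted p = 0.00133) and 4.21 (adjusted p = 0.00131). In wild type 22% of probe sets lay at or below DRT100, a level not shown to lie above background, so its difference is not exact. Several named genes that rose in drying wild type stood lower. HSP17.6C and HSP22 were lower, with changes of -2.82 (adjusted p = 0.00307) and -2.28 (adjusted p = 0.00253), and COR15A was 4.5-fold lower (SE 0.517, adjusted p = 0.0315). The glycosyltransferase genes UGT76E12 (AT3G46660) and UGT76E11 (AT3G46670), which rose by 3.86 (adjusted p = 0.000593) and 2.73 (adjusted p = 0.0026) in wild type, were 15.2-fold (SE 0.388, adjusted p = 0.001) and 13.8-fold lower (SE 0.399, adjusted p = 0.00132). The COR15A call ended without any 1 of the 4 arrays, at adjusted p = 0.193 and 0.104 without the first and second wild-type replicate and 0.0974 and 0.12 without the first and second atx1 replicate. Of the 8 dehydration-induced protein genes, 4 were lower and 6 when adjusted over the list alone, with a median of -1.70 (camera adjusted p = 0.000821; adjusted p = 0.426 with an estimated correlation). Of the 7 light harvesting and photosystem genes, 3 were higher and 4 when adjusted over the list alone, with a median of 0.76 (camera adjusted p = 0.018; adjusted p = 0.621 with an estimated correlation; adjusted p = 0.106 with the GAPDH covariate, in a range of 0.00841 to 0.106). LHCB4.3 (AT2G40100), an antenna protein gene of photosystem II, was 6.53-fold higher (SE 0.313, adjusted p = 0.00202). Of the 9 expansin and xyloglucan endotransglucosylase genes 2 were higher, and the list did not pass (camera adjusted p = 0.288; adjusted p = 0.621 with an estimated correlation). The GAPDH difference was 1.468 in these atx1 arrays and 0.569 in those of wild type, and the hybridization controls averaged 9.845 and 8.637.

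Other genes that differed under water deficit were not called in the wild-type response. GILT was 101-fold higher in atx1 under water deficit, at 10.57 ± 0.5 against 3.906 ± 0.298 (SE 0.262, adjusted p = 2.56e-05). DELTA-VPE (AT3G20210), a vacuolar processing enzyme gene of the seed coat, was 31.7-fold higher, at 8.915 ± 0.167 against 3.928 ± 0.104 (SE 0.185, adjusted p = 2.35e-05), and CYP71B31 17.3-fold higher (SE 0.228, adjusted p = 9.88e-05). In wild type only 14.3%, 15% and 11.2% of probe sets lay at or below GILT, DELTA-VPE and CYP71B31, levels not shown to lie above background, so these folds are not exact. The count was 2751 probe sets, 1674 higher and 1077 lower in atx1. Median centring moved the median difference from 0.01 to -0.22 and split the calls into 966 higher and 1628 lower. The count was 504 without wild-type replicate 1, 1317 without wild-type replicate 2 and 888 without atx1 replicate 1, and it was 1785 and 1460 with the hybridization and GAPDH covariates. Of the 22 named genes called, 12 were called whichever array was left out, COR15A not among them, and 13 were called with the GAPDH covariate.

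**Figure D3:**
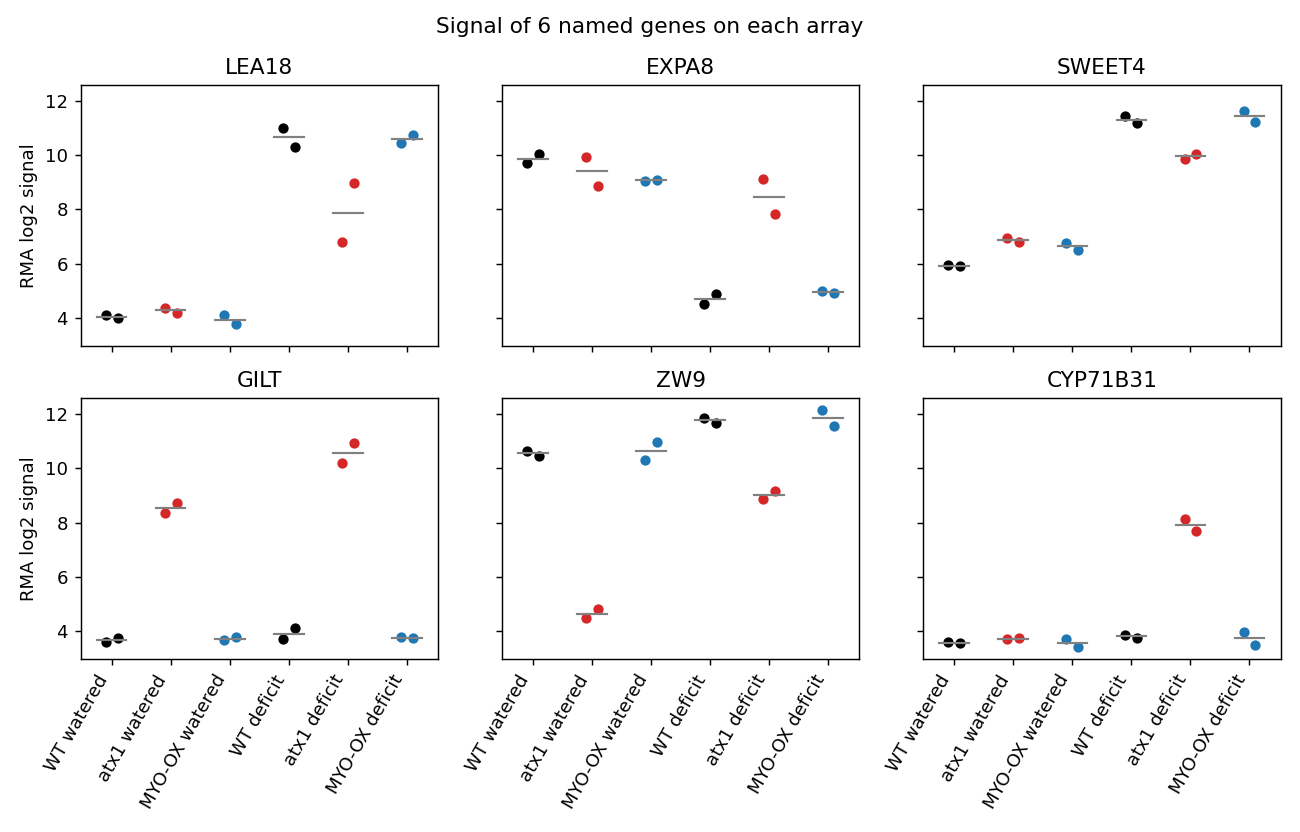
RMA log2 signal (vertical axis) of LEA18, EXPA8, SWEET4, GILT, ZW9 and CYP71B31 in the 6 groups, with each point an array (n = 2 per group) and each grey line the mean of its group. GILT is above 8 in atx1 arrays and near 4 elsewhere, CYP71B31 reaches 7.915 in atx1 under water deficit alone, and EXPA8 averages 4.695 in wild type and 4.965 in MYO-OX under water deficit but 8.474 in atx1.

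Under water deficit atx1 was also compared with MYO-OX, with the same atx1 arrays as in the comparison with wild type, so the 2 comparisons are not independent. GILT was 111-fold (SE 0.262, adjusted p = 2.16e-05), DELTA-VPE 28.8-fold (SE 0.185, adjusted p = 2.16e-05), EXPA8 11.4-fold (SE 0.442, adjusted p = 0.00292) and BCAT4 9.45-fold higher in atx1 (SE 0.428, adjusted p = 0.00356). The levels of GILT and DELTA-VPE in MYO-OX were again low, with 8.92% and 17.8% of probe sets at or below them. HSP22 was 3.85-fold and ZW9 7.15-fold lower (adjusted p = 0.00529 and 0.00115). Of the 8 dehydration-induced protein genes, 5 were lower and 6 when adjusted over the list alone (camera adjusted p = 0.000408; adjusted p = 0.568 with an estimated correlation). Of the 7 light harvesting and photosystem genes 1 was higher, LHCB4.3, and 4 when adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.611 with an estimated correlation). That list test ended without atx1 replicate 1 (adjusted p = 0.0586), without MYO-OX replicate 2 (adjusted p = 0.0883), with dim probe sets left out (adjusted p = 0.075) and with the GAPDH covariate (adjusted p = 0.0591), in a range of 0.00984 to 0.0883. The GAPDH difference was 1.468 in atx1 and 0.893 in MYO-OX. limma called 2539 probe sets, 1529 higher and 1010 lower, and after median centring, which moved the median difference from -0.02 to -0.26, 881 higher and 1578 lower. The count was 738 without atx1 replicate 1, 1417 without MYO-OX replicate 1, 646 without MYO-OX replicate 2 and 1196 with only the arrays of the comparison. With these arrays 14 of the 22 named genes stayed called, and HSP22 did not (adjusted p = 0.0576, in a range of 0.00193 to 0.0576).

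MYO-OX and wild type were compared within each water state to ask what the transgene changed. No probe set passed limma in watered plants, where 606 had an unadjusted p under 0.05 and the smallest adjusted p was 0.278, and none passed under water deficit, where 147 had an unadjusted p under 0.05 and the smallest adjusted p was 1. Both counts lie below the share of 0.05 of the 22746 probe sets expected without any change, so they are no sign of effects. The p values thus ran high in these comparisons, and such tests can miss real changes. COR15A differed by 0.39 (adjusted p = 1) and 0.35 (adjusted p = 1). No member of a list fixed beforehand was called, and no such list passed, the dehydration-induced protein genes having camera adjusted p = 0.388 watered and 0.575 under water deficit (adjusted p = 0.83 and 0.878 with an estimated correlation). Of the lists written from the annotation, 4 passed without a called member, and none passed with an estimated correlation. In watered MYO-OX the autophagy genes lay higher, with a median of 0.53 (camera adjusted p = 0.00675; adjusted p = 0.788 with an estimated correlation), but did not pass without MYO-OX replicate 1 (adjusted p = 0.817) or with repeated quantile normalization (adjusted p = 0.0588), in a range of 0.00305 to 0.817. The plastid-encoded photosystem and cytochrome genes lay higher, with a median of 0.40 (camera adjusted p = 0.0118; adjusted p = 0.83 with an estimated correlation), but did not pass without wild-type replicate 1 (adjusted p = 0.385), without MYO-OX replicate 2 (adjusted p = 0.467) or with repeated quantile normalization (adjusted p = 0.105), in a range of 5.31e-05 to 0.467. The UDP-glycosyltransferase genes lay lower, with a median of -0.08 (camera adjusted p = 0.0366; adjusted p = 0.788 with an estimated correlation), and did not pass without any 1 of the 4 arrays, at adjusted p = 0.117 and 0.0729 without the first and second wild-type replicate and 0.326 and 0.202 without the first and second MYO-OX replicate. They did not pass with the replicate block either (adjusted p = 0.0539), in a range of 0.013 to 0.326. Under water deficit the jasmonate and defence genes lay lower in MYO-OX, with a median of -0.20 (camera adjusted p = 0.00102; adjusted p = 0.112 with an estimated correlation), but did not pass without MYO-OX replicate 2 (adjusted p = 0.111) or with the hybridization (adjusted p = 0.103) or GAPDH covariate (adjusted p = 0.23), in a range of 7.62e-05 to 0.23. The watered count was 2 without wild-type replicate 1 and 410 without MYO-OX replicate 2, and with the GAPDH covariate 1 probe set was called in each state.

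The difference between the responses was tested to ask which genes responded differently in atx1 and in wild type. CYP71B31 rose by 4.19 in atx1 and changed by 0.22 in wild type, a difference of 3.97 (SE 0.322, adjusted p = 0.00991), and DELTA-VPE by 2.93 and -0.14, a difference of 3.07 (SE 0.261, adjusted p = 0.00991). In watered and drying wild type 5.52% and 11.2% of probe sets lay at or below CYP71B31, and 19.6% and 15% at or below DELTA-VPE. These levels are not shown to lie above background, so the 2 differences are not exact. ZW9, low in watered atx1, rose by 4.36 in atx1 and by 1.21 in wild type, a difference of 3.15 (SE 0.397, adjusted p = 0.0359). IAA29 fell by 3.32 in wild type and changed by -0.35 in atx1, a difference of 2.97 (SE 0.385, adjusted p = 0.0377). It was already low in watered atx1, at 5.097 ± 0.575, against 7.793 ± 0.127 in watered and 4.476 ± 0.0263 in drying wild type. The difference of responses may thus largely restate its lower watered level. SWEET4 rose by 5.38 in wild type and 3.08 in atx1, a difference of -2.30 (SE 0.271, adjusted p = 0.032), and the glutamate receptor gene ATGLR1.2 (AT5G48400) stood at 6.646 ± 0.322 in drying wild type and 4.348 ± 0.0868 in drying atx1, a difference of responses of -2.22 (SE 0.313, adjusted p = 0.0486). At or below ATGLR1.2 lay 22.5% of probe sets in watered wild type, 20.2% in watered atx1 and 25.6% in drying atx1. These levels are not shown to lie above background either, so its difference is not exact. COR15A differed by -2.33 without passing (SE 0.731, adjusted p = 0.299), as did EXPA8 by 4.24 (adjusted p = 0.0538), HSP17.6C by -2.75 (adjusted p = 0.0896) and HSP22 by -2.13 (adjusted p = 0.0882). None of the 8 dehydration-induced protein genes passed limma over all probe sets, and 4 had a smaller rise in atx1 when adjusted over the list alone, with a median of -2.18 (camera adjusted p = 1.87e-05; adjusted p = 0.408 with an estimated correlation). The 7 light harvesting and photosystem genes had a median difference of 0.55 with 0 called (camera adjusted p = 0.0105; adjusted p = 0.408 with an estimated correlation; adjusted p = 0.153 with the GAPDH covariate, in a range of 0.00167 to 0.153). For the same contrast the GAPDH difference rose in atx1 from 0.721 to 1.468 and changed in wild type from 0.727 to 0.569.

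Of all probe sets, 40 differed in response between atx1 and wild type, 24 with a positive and 16 with a negative difference, and 2320 had an unadjusted p under 0.05. In 30 of the 40 the atx1 response was the smaller. The lowest adjusted p of the 40 belonged to AT2G42560, which has no symbol and so was not named by the rule. It rose by 6.53 in wild type, 5.998 in MYO-OX and 0.23 in atx1, a difference of -6.29 (SE 0.434, adjusted p = 0.00756 in limma). Median centring moved the median difference from -0.01 to -0.15 and gave 55 calls, 21 positive and 34 negative, and repeated quantile normalization 72, 34 positive and 38 negative. The calls fitted with the replicate number as a block were 24. They were 99 with an intensity trend and a robust prior and 5 with the GAPDH covariate. No call was left without watered wild-type replicate 1, watered atx1 replicate 1 or watered atx1 replicate 2, while 2 were left without watered wild-type replicate 2, 1 without water-deficit wild-type replicate 1, 19 without water-deficit wild-type replicate 2 and 14 without water-deficit atx1 replicate 1. Without water-deficit atx1 replicate 2 there were 107. None of the 6 named genes was called whichever array was left out. With the replicate block ZW9 (adjusted p = 0.055, in a range of 0.023 to 0.189 over all alternatives) and ATGLR1.2 (adjusted p = 0.0633, in a range of 0.0274 to 0.217) did not pass. With the GAPDH covariate only CYP71B31 and DELTA-VPE passed, with the hybridization covariate ZW9 and ATGLR1.2 did not, and IAA29 did not pass after median centring (adjusted p = 0.052, in a range of 0.0269 to 0.189). With only the arrays of the comparison IAA29 and ATGLR1.2 did not pass. Between MYO-OX and wild type, limma called 0 probe sets for the difference of responses. There 276 had an unadjusted p under 0.05, fewer than the share of 0.05 of 22746 expected without any change.

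Finally, effects of each genotype were compared between water states and with each other. Of the probe sets that differed between atx1 and wild type in watered plants, 357 (71.3%) differed in the same direction under water deficit, 222 higher and 135 lower, and 4 in the opposite one. GILT, ZW9, ECS1 and PUB19 were among them. Across probe sets, which are not independent replicates, the atx1 effects in both states correlated at r = 0.568 (rho = 0.486), and the MYO-OX effects at r = 0.0381 (rho = -0.0156), a value that was 0.14 without watered MYO-OX replicate 1, -0.0368 without watered MYO-OX replicate 2 and -0.0455 without water-deficit wild-type replicate 2. The effects of atx1 and MYO-OX within a state share the wild-type arrays, and simulated effects without any real change gave r = 0.5 with a covariance of 0.0697. Observed were r = 0.171 with a covariance of 0.0381 in watered plants and r = 0.218 with a covariance of 0.0437 under water deficit. The simulation treated the arrays as independent. In the watered groups arrays of the same number deviated together, with correlations of 0.514 to 0.561. Such a shared shift cancels in these differences and would make the simulated covariance too high. Under water deficit the deviations of wild type correlated at -0.266 with those of atx1 and -0.286 with those of MYO-OX. The direction of any such error is therefore not known there. With 2 control arrays per state, a split would leave 1 for each genotype and was not made. Part or all of each correlation may come from the shared controls, which alone gave a higher covariance in the simulation. The watered r was 0.33 and 0.35 without the first and second wild-type replicate and 0.0778 without atx1 replicate 1. The water-deficit r was -0.0989 without MYO-OX replicate 1 and 0.519 without wild-type replicate 2. Effects from different states, which share no array, correlated at r = 0.156 (rho = 0.176) for atx1 watered against MYO-OX under water deficit and r = 0.0654 (rho = 0.0782) for the reverse pairing. The first was 0.0993 without water-deficit wild-type replicate 1 and 0.101 without water-deficit MYO-OX replicate 2, and the second 0.0146 without watered wild-type replicate 2 and -0.0478 without watered MYO-OX replicate 1.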

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

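The tests with the actin and ubiquitin controls, of 1 common factor, of probe mismatches and of the share of genes on chromosome 2 were chosen only after the result was seen. Those with the hybridization and GAPDH covariates were added after the comparisons were seen, with bounds written before the shares they gave were known.

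A test of the difference between the genotypes' responses singled out 40 probe sets whose response to water deficit differed between atx1 and wild type. The same test singled out 6 named genes, with differences of 2.97 in IAA29, 3.97 in CYP71B31, 3.15 in ZW9, 3.07 in DELTA-VPE, -2.3 in SWEET4 and -2.22 in ATGLR1.2. The highest adjusted p with 1 array left out was 0.189 for IAA29, ZW9 and SWEET4, 0.0865 for CYP71B31 and DELTA-VPE and 0.217 for ATGLR1.2. Outside the measured genes, control probe sets stood above their level in watered wild type on the atx1 water-deficit arrays, by 1.36 for the spiked hybridization controls and by 0.74 for the GAPDH 3'-minus-5' difference.

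Over the probe sets called in MYO-OX, the atx1 response was 0.484 of the wild-type response, by a test of the difference. With the actin and ubiquitin 3'-5' differences as covariates the share was 0.47 and 0.454, and with 1 array left out 0.348 to 0.569 and 0.115 to 0.581. Both shares lay under 0.8, the bound set against RNA degradation as those controls read it. With 1 mean per group, however, the slope of each covariate came only from differences between the replicates of a group. This holds for the GAPDH and hybridization covariates too. The shares therefore cannot decide whether degradation accounts for the smaller response, and that explanation stays open. RNA degradation as GAPDH reads it cannot be told apart from the genotype, since that covariate raised the share to 0.996 (0.896 to 1.15 with 1 array left out), the actin and ubiquitin covariates did not, and both atx1 water-deficit arrays lie beyond all others in it. The actin difference also had its highest group mean there, 3.378 against at most 3.15, and atx1 replicate 1 under water deficit was the highest single array in actin, 3.577, and ubiquitin, 1.35. The bound written beforehand for GAPDH as the cause, at least 0.9, was met. After that value was seen, the same answer was also required of actin and ubiquitin, which did not give it, so the explanation was left open. Labelling or hybridization differences also stay open, although the share with the hybridization covariate, 0.699, met the bound written beforehand against them, under 0.8. It ranged from 0.614 to 0.838 with 1 array left out, so the bound was not met by more than its spread, and the share did not pass the test of the difference (adjusted p = 0.155). A milder water deficit also stays open: residuals around 1 common factor were 1.53 times those expected from replicates (1.21 to 1.61 with 1 array left out), which does not exclude that the plants dried less, and 0 samples have a relative water content of their own in the labels.

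Among the 357 probe sets that differed in the same direction between atx1 and wild type in both water states, 37.8% were lower in atx1 (upper confidence limit 43.1%). Probe mismatches to another accession background would lower signals, so the share argues against them as the whole cause as the values were deposited. It was 53.8% of 333 after median centring and 48.9% of 362 after repeated quantile normalization, so a part in them stays open. Expression differences between accession backgrounds were not tested. A chromosome block carried along with the mutant allele would lie on chromosome 2 with ATX1. Of the 183 genes placed, 23 (12.6%, upper confidence limit 18.3%) lie there, against 16.4% of all genes placed, which argues against genes of such a block as the whole of the pattern. Effects of a block on the 160 genes elsewhere were not tested. For the 23 genes a block cannot be told apart from an effect of the mutation, because in the whole set 3 neighbouring pairs were called against a mean of 2.507 in shuffled orders, a ratio of 1.2, and the pairs are too few. That ratio met the bound written beforehand against a block, under 1.5, but the bound took no account of the spread of so few pairs, and the explanation was left open after the value was seen.

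No probe set was called by limma between watered MYO-OX and wild type, with 606 at an unadjusted p under 0.05. That is fewer than the share of 0.05 of all 22746 probe sets expected without any change. The explanation that the watered MYO-OX replicate 1 array inflates the spread cannot be told apart from a difference too small to call. Leaving that array out left 0 calls (630 at an unadjusted p under 0.05 in limma), while leaving out replicate 2, which removes the same spread within the group, gave 410. The bound written beforehand, at most 5 calls without replicate 1, was met, but it was wrong by design: with 2 arrays in the group, leaving out either removes the same spread, and the arrays gave opposite outcomes. The explanation was therefore left open after that result was seen. This group had the lowest correlation between replicates, 0.928. An absence of any effect of the transgene was not shown, and MYO1 levels were not analysed here.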

How the results depend on the processing

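The hybridization and GAPDH covariates and the crossed block were chosen only after the result was seen. Where no reason is given, the cause was not tested.

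With 1 probe set per gene, 13355 were tested, and with fewer tested the calls under water deficit against watered were 2291 in wild type, 352 in atx1 and 2909 in MYO-OX. They were 248 for atx1 against wild type and 286 against MYO-OX in watered plants, 1283 and 1201 under water deficit, and 23 for the difference of the atx1 response. With only the arrays of the comparison, hence fewer arrays, limma called 0 in the atx1 response (3599 at an unadjusted p under 0.05), 1176 in the MYO-OX response, 60 for watered atx1 against wild type, 0 for watered atx1 against MYO-OX (1951 at an unadjusted p under 0.05) and 1196 for these under water deficit.

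For the difference of the atx1 response, the replicate block gave 24 calls, repeated quantile normalization 72 and an intensity trend with a robust prior 99. With the block the other counts stayed within 1.5 times those reported. Of the named genes, 2 of 6 were no longer called for that difference and 1 of 22 for atx1 against wild type under water deficit, and all named calls of the other comparisons were kept. The deviations of replicate 1 from the group mean correlated at 0.514 to 0.561 between the 3 watered groups, at -0.286 to 0.0828 between wild type under water deficit and the other groups, and at 0.0337 to 0.499 between the remaining pairs. The samples with the same number thus deviated together in the watered groups but not in all groups. A block crossed for wild type under water deficit gave 3806 calls against atx1 and 0 against MYO-OX (266 at an unadjusted p under 0.05 in limma).

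The hybridization covariate gave 2259 calls in the atx1 response, 908 for watered atx1 against MYO-OX and 1785 for atx1 against wild type under water deficit. With it the atx1 effects of both states correlated at 0.634, the MYO-OX effects at 0.112, both effects under water deficit at 0.44, and the watered atx1 with the water-deficit MYO-OX effect at 0.334. The share of the wild-type response seen in atx1 was 0.699.

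The GAPDH covariate gave 3908 calls in the atx1 response, 986 for watered atx1 against wild type and 1060 against MYO-OX, 1460 for atx1 against wild type under water deficit, 1 for MYO-OX against wild type in each state and 5 for the difference of the atx1 response. The wild-type response correlated at 0.889 with that of MYO-OX and 0.626 with that of atx1. The atx1 effects correlated at 0.487, the MYO-OX effects at -0.206, both effects under water deficit at 0.576, and the effects of different states at 0.1 and -0.197. The share was 0.996.

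With 1 array left out, the lone sample of its group was assumed to vary like the other groups. The calls ranged from 1441 to 2999 in the wild-type response, 177 to 631 in that of atx1 and 2686 to 7766 in that of MYO-OX. In watered plants they ranged from 101 to 220 for atx1 and 0 to 410 for MYO-OX against wild type, and from 201 to 2689 for atx1 against MYO-OX. Under water deficit they ranged from 504 to 2288 for atx1 against wild type and 646 to 1997 against MYO-OX. The difference of responses gave 0 to 107 calls for atx1 and 0 to 1 for MYO-OX. The responses correlated at 0.845 to 0.937 for wild type and MYO-OX, 0.593 to 0.789 for wild type and atx1, and 0.602 to 0.774 for MYO-OX and atx1. The atx1 effects of both states correlated at 0.455 to 0.604 and the MYO-OX effects at -0.0455 to 0.14. Effects of both genotypes correlated at 0.0778 to 0.35 watered, -0.0989 to 0.519 under water deficit, and 0.0993 to 0.169 and -0.0478 to 0.0975 across states. The share ranged from 0.394 to 0.58, and list tests called from 58 to 90 against 72.

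Of the gene list results, 571 kept their direction and side of the threshold under the other alternatives and 90 did not pass, against 244 and 75 with 1 array left out. The list of plastid-encoded NDH, ATP synthase and other enzymes reversed direction in the difference of the atx1 response without wild-type water-deficit replicate 1 (adjusted p = 0.782 in limma, in a range of 3.97e-06 to 0.782 with 1 array left out). The levels of ATX1 and MTM1 were not run, since no probe set was named for them. Signal near background limits what the dim probe sets can show.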

Other observations

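Only the lists written from the annotation are described here, which were added after the lists fixed beforehand. The test with the GAPDH covariate was chosen after the result was seen.

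Nuclear genes for chloroplast and chlorophyll functions fell under water deficit in 20 of 34 measured members in wild type and 23 in MYO-OX, with 1 higher in each, and in 1 in atx1 (camera adjusted p = 1.44e-10, 3.32e-08 and 1.2e-08; adjusted p = 0.254, 0.259 and 0.314 with an estimated correlation). With the GAPDH covariate the atx1 list gave an adjusted p of 0.00206, in a range of 1.92e-09 to 0.00206. The hybridization controls averaged 9.845 in atx1 under water deficit and 8.889 in watered atx1, and the GAPDH difference was 1.468 and 0.721. CHLM, for a chlorophyll synthesis enzyme, fell by 2.72 in wild type (adjusted p = 0.000253 in limma). Of 10 autophagy genes 5 rose in wild type (camera adjusted p = 0.000395; adjusted p = 0.567 with an estimated correlation), among them ATG8B by 1.59 (adjusted p = 0.00983) and ATG3 by 1.15 (adjusted p = 0.00556).

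Of 47 measured UDP-glycosyltransferase genes, 12 were lower in atx1 than in wild type under water deficit, with a median of -0.38 (camera adjusted p = 4.16e-07; adjusted p = 0.282 with an estimated correlation). UGT73B5 was among them, with a change of -2.39 (adjusted p = 0.0118 in limma). The hybridization controls averaged 9.845 and 8.637 and the GAPDH difference was 1.468 and 0.569 in these groups. In watered plants 1 of the 47 was lower in atx1 (camera adjusted p = 0.00104; adjusted p = 0.309 with an estimated correlation). The 7 calmodulin-like genes had a median of -1.36 in watered atx1 against wild type, with 0 called by limma over all probe sets (camera adjusted p = 0.0135; adjusted p = 0.309 with an estimated correlation).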
